A study of Mus musculus with 4 samples.

How the data were processed

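RNA was measured on 4 whole-transcript arrays from 2 mouse tumour cell lines, named 167 and 365 in the labels, each infected with a retrovirus carrying Smarcb1 or with the empty retrovirus. Per the labels, total RNA was taken 3 days after infection, purified on spin columns, labelled with biotin by a whole-transcript sense-target method and hybridised to 1 array per line and vector. The deposited values are log2 probe set signals, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and combines the probes of a probe set. Versions, settings, the annotation release and a genome build are not given in the sources used here, so no coordinates are printed. The deposited log2 values were used as they stand. Their median over all 35556 probe sets was 5.04 and 5.07 for line 167 with empty vector and with Smarcb1, and 5.03 and 5.06 for line 365. Quantile-normalized arrays share nearly the same distribution, so a change of total RNA content per cell cannot be seen in such values.

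Gene names came from the platform annotation supplied with the value table. It gives 1 gene symbol for 21789 probe sets and several for 1621, and it does not list 12146, which stay unnamed here. Entrez identifiers of 21698 of the 21789 probe sets were found in a RefSeq gene table (assembly GRCm38.p6), and 0 symbols needed an update. The 21789 probe sets stand for 19938 genes, of which 999 have more than 1 probe set. For those genes the probe set with the highest mean over the 4 arrays was used. Genes with a mean below the 30th percentile (log2 4.27) were left out, which left 13956 tested genes and 5982 below the limit. A tested gene can lie below this limit on single arrays, where signal above background was not shown, and the size of a change from or to such a level is uncertain. Of the 10 genes fixed by name, 2 are not analysed here, and a list of mitochondrially encoded transcripts is not analysed here either.

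Each line had its own control, so the model held a term for the cell line and a term for the vector, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The p-values are two-sided and were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The pairing follows from the cell lines. Arrays of the same line deviated together from the means of their vector group, with a correlation of 0.770 across genes. The residual has 1 degree of freedom and consists of the difference between the lines in their response to Smarcb1. eBayes added 3.75 prior degrees of freedom. The standard errors (SE) given are moderated across genes by eBayes, so they are not the spread between the 2 lines of a gene. The response of a single line has no replicate and no test, and neither has the difference between the responses of the lines. Each p-value sets a fitted effect, of the vector or of the line, against this residual after moderation across genes. The only replication is thus that of 2 tumour lines, and nothing in the labels speaks of repeat cultures of a line. For arrays, their number limits the precision.

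A set of 35 gene lists (pathways, complexes, gene families, cell type markers and ribosomal protein genes) was written before the data were examined. It held 768 entries, of which 709 matched a gene, and the 34 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same test was run with a correlation estimated from the residual, which rests on 1 degree of freedom. Each list's median change was also placed among 10000 random lists of the same size matched on mean signal. The p-values of members were also adjusted over their list alone, for each of the 34 lists separately and without a correction across lists. Set tests between the cell lines were added after the data were seen.

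Named genes followed a rule written before the data were examined. It took 10 genes fixed by name, then the 12 largest rises and 12 largest falls past the test with the same sign in both lines. Where fewer passed, the places were filled with the genes of largest mean change that moved at least 1.5-fold the same way in both lines. It also took up to 4 members of smallest p from each list described, the 8 largest differences each way between the lines, and the 5 largest opposite or line-specific changes each way. Predicted genes without a proper name and olfactory or vomeronasal receptor genes were passed over in the ranked parts. Some genes that the rule takes are not reported here.

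The gene-level fit was tested on simulated data in 20 runs of 13956 genes with 200 changed genes each. Gene means, line differences and the prior of the variances were taken from the arrays and the fit to them. For the comparison of Smarcb1 with empty vector it recovered 17.6% of genes changed 2-fold, 93.5% at 4-fold, 98.8% at 8-fold and 99.7% at 16-fold. Of all calls, 7.61% were false, and 4 of 20 runs without any change gave a call, with at most 5 genes. Each simulated change was of equal size in both lines, with independent noise. The rates therefore do not cover genes whose response differs between the lines.

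The alternatives were no filter and a filter at the 50th percentile, eBayes without the trend or with robust estimation, median centring, quantile normalization over the named genes, cyclic loess, other handling of several probe sets, other thresholds, a fit without the cell line, arrays or lines left out, camera on ranks and an estimated inter-gene correlation. Table columns of samples other than these 4 numbered 0.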

Results

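Smarcb1 is a core subunit of the SWI/SNF chromatin remodelling complex and the tumour suppressor lost in malignant rhabdoid tumours. Lines 167 and 365 came from soft tissue tumours that had lost Smarcb1 in mice lacking p53. Each line was infected with the pMIG retrovirus carrying Smarcb1 or with the empty virus, and RNA was profiled 3 days later on whole-transcript arrays, 1 array for each line and vector, 4 in all. The early time point was chosen by the submitters to favour genes under direct control of Smarcb1. Across the tested genes, with 1 probe set per gene, the 2 arrays of line 167 correlated at r = 0.959 and those of line 365 at r = 0.970. The empty-vector arrays of both lines correlated at r = 0.907 and the Smarcb1 arrays at r = 0.922. These correlations are across genes, which are not independent replicates.

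Smarcb1 itself was checked first. Its signal (probe set 10370025) rose from log2 4.61 to 7.83 in line 167 and from 6.01 to 9.61 in line 365. The mean increase was 3.41 ± 0.20 (moderated SE), or 10.6-fold, with limma adjusted p = 0.0371. The vector labels therefore match the signal in both lines. Which exons the probes cover is not given in the sources used here, so transcript from the vector and from the cells is not separated.

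Smarcb1 re-expression raised 9 genes in the limma fit and lowered 0, out of 13956 tested, at an adjusted p below 0.05. Akr1c18, a hydroxysteroid dehydrogenase that inactivates progesterone, rose by log2 4.18 ± 0.18 (moderated SE). Serpinb1a, an inhibitor of neutrophil serine proteases, rose by 4.11 ± 0.25. Nrp1, a co-receptor for semaphorins and vascular endothelial growth factor, rose 14.3-fold (3.84 ± 0.18), and Efnb2, a membrane-bound ligand of Eph receptors, rose 12.7-fold (3.67 ± 0.19). The secreted serine protease gene Prss23 rose 10.5-fold, Phldb2, which encodes a cortical protein that anchors microtubules, 9.24-fold, and the basement membrane protein gene Tinagl1 8.14-fold. The guanine deaminase gene Gda rose by log2 3.36. The ninth gene was Smarcb1. Their adjusted p-values lay between 0.0315 (Akr1c18, Nrp1 and Tinagl1) and 0.0371, and all 9 were higher in both lines.

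The p-value takes its residual from the difference between the lines, so genes that pass tend to have similar single-line values by the way they were chosen. Akr1c18 changed by 4.06 in line 167 and 4.29 in line 365, Nrp1 by 3.76 and 3.91, Efnb2 by 3.74 and 3.59, Phldb2 by 3.22 and 3.20, and Tinagl1 by 2.96 and 3.09 on the log2 scale. Serpinb1a had the widest gap, with 3.72 and 4.50. Akr1c18 and Serpinb1a started from the dimmest controls, at log2 3.40 and 3.39 in line 167 and 3.46 and 3.39 in line 365, whereas Tinagl1 started at 6.68 and 8.86. Those dim controls lie below the filter level of 4.27, as does the line 365 control of Gda at 4.16, and signal above background was not shown for them, so the sizes of these changes are uncertain.

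**Figure D1:**
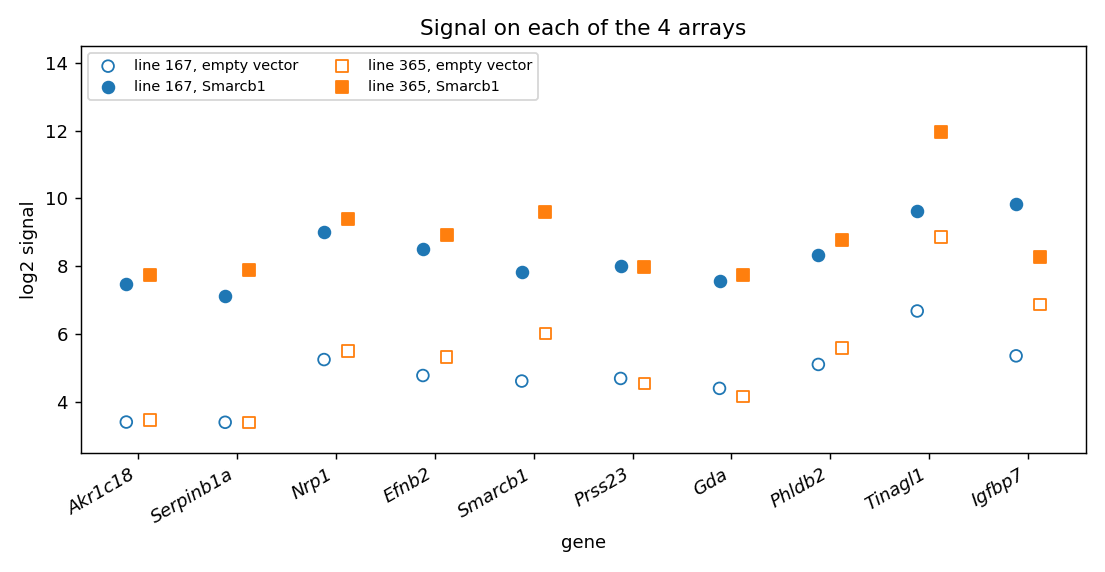
Log2 signal on each of the 4 arrays (vertical axis) for the 9 genes past the test and for Igfbp7 (horizontal axis), with open symbols for empty vector, filled symbols for Smarcb1, circles for line 167 and squares for line 365. For each of the 9 genes both filled symbols lie above both open ones, and Igfbp7 differs by 4.49 in line 167 and by 1.41 in line 365.

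Several genes had large mean changes and did not pass. Paired values here and in the lists give the log2 change in line 167 and then in line 365. Mmp3, the matrix protease stromelysin, was higher by 3.74 in line 167, from a control at 3.93, and by 5.45 in line 365 (limma adjusted p = 0.0694). Ceruloplasmin (Cp), a copper-carrying ferroxidase, was higher by 5.32 and 2.93 (adjusted p = 0.118), and neuritin (Nrn1), which promotes neurite outgrowth, by 4.95 and 3.05 (adjusted p = 0.0865). Igfbp7, a secreted protein that binds insulin-like growth factors, was higher by 4.49 in line 167 and by 1.41 in line 365. Its mean change was 2.95 ± 0.73 (moderated SE), with limma adjusted p = 0.278. Cell cycle and chromatin genes fixed by name did not pass. Cdkn2a changed by -0.14 and 0.08, the cyclin D1 gene Ccnd1 by -0.19 and 0.21, the Polycomb methyltransferase gene Ezh2 by -0.25 and 0.16, and Cdkn1c by -0.55 and 0.04. The Hedgehog target Gli1 changed by -0.01 and -0.27 and the receptor gene Ptch1 by 0.67 and -0.36, and adjusted p for these 6 genes was 0.718 or higher.

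Among lower genes the smallest limma adjusted p was 0.0620, for the neurexophilin gene Nxph3, with -2.04 in line 167 and -2.10 in line 365. Slc40a1, which encodes the iron exporter ferroportin, gave -2.01 and -2.81 (adjusted p = 0.0846). The opioid precursor gene Penk gave -2.88 and -1.60 (adjusted p = 0.132), and the neurofilament genes Nefl and Nefm gave -3.42 and -0.83 (adjusted p = 0.323) and -2.36 and -1.20 (adjusted p = 0.177). Pdzd2 was at -1.57 and -1.86 (adjusted p = 0.0865), and Npvf, a neuropeptide precursor gene, at -1.55 and -1.44 (adjusted p = 0.0940). Other large decreases were Btg2, an antiproliferative p53 target (-0.97 and -2.53), S100a5 (-3.43 and -0.83), Tmem267 (-2.37 and -1.26) and Gchfr, a regulator of tetrahydrobiopterin synthesis (-1.19 and -1.94).

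At an unadjusted p below 0.05 the limma fit held 1613 genes, 793 of them lower, where chance alone gives 697.8. The count past the adjusted threshold moved with the settings, from 9 to 68 genes without the filter, 101 with a filter at the 50th percentile, 71 after quantile normalization, 28 after cyclic loess and 103 at an adjusted p below 0.10. Without the cell line in the model 0 genes passed limma's test, with 450 at an unadjusted p below 0.05.

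**Figure D2:**
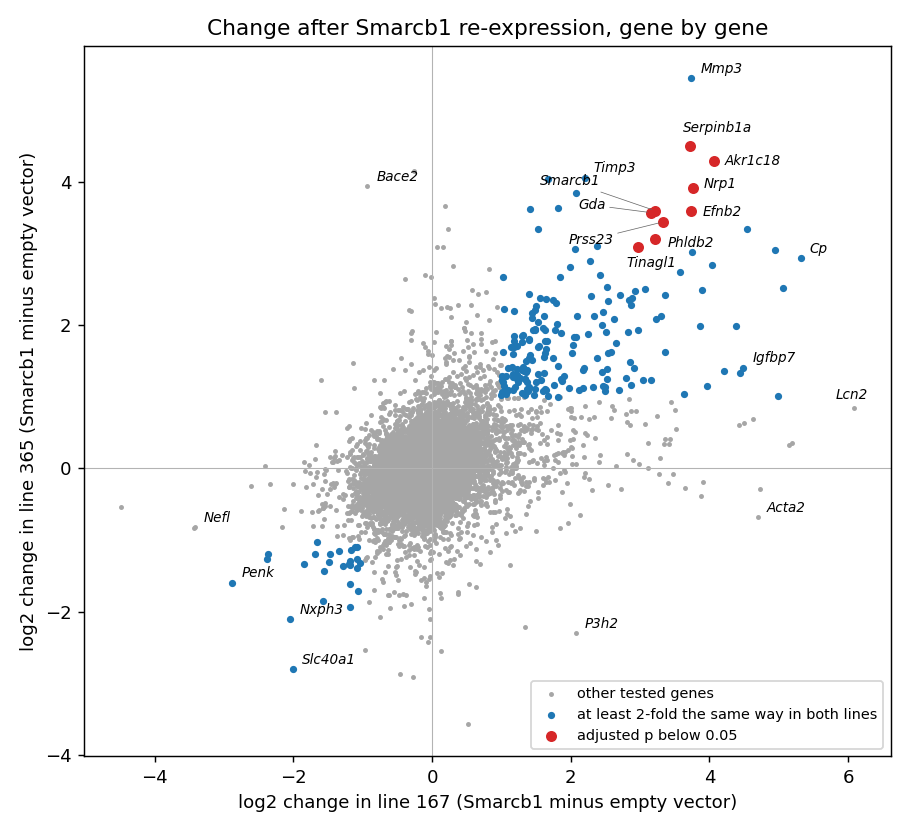
Log2 change after Smarcb1 re-expression in line 167 (horizontal axis) and line 365 (vertical axis) for the 13956 tested genes, 1 point per gene, with the 9 genes past the test in red and the other genes changed at least 2-fold the same way in both lines in blue. The upper right holds 186 genes at least 2-fold higher in both lines and the lower left 26 genes lower in both.

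The lines shared many large increases. At least 2-fold higher in both lines were 186 genes, against 13.5 that independent lists of this size would share, and 26 were at least 2-fold lower in both, against 2.43. Opposite 2-fold changes occurred in 6 genes. Line 167 had 475 genes at least 2-fold higher and 208 lower, and line 365 had 397 and 163. Across genes, which are not independent replicates, the changes of the lines correlated with Pearson r = 0.441 and Spearman rho = 0.316, and 60.1% of genes had the same sign. The arrays of each line have their own control, so no control is shared. These counts carry no p-value.

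Genes of the extracellular matrix rose as a set, with the larger median in line 167. The median change of the 32 tested members was 0.98 in line 167 and 0.02 in line 365 (camera adjusted p = 2.09e-07, and adjusted p = 0.789 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 5 were higher and 0 lower. Tenascin C (Tnc) was at 2.93 and 2.48, fibulin 2 (Fbln2) at 1.78 and 2.31, fibronectin (Fn1) at 3.90 and 2.48, and Col5a1 at 1.25 and 1.27. Against random lists of the same size, the line 365 median lay at the 68.3 percentile.

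Integrin and matrix protease genes rose as a set, with medians of 0.33 and 0.26 over 29 genes (camera adjusted p = 6.68e-05, and adjusted p = 0.789 with an estimated correlation), 14 of them higher in both lines. Of the members, 0 passed over all genes and 6 were higher adjusted over the list alone, among them Mmp3, the membrane-anchored protease gene Mmp14 (1.10 and 1.09), the collagenase gene Mmp13 (1.31 and 1.42) and the protease inhibitor gene Timp3 (2.20 and 4.06). Contractile and actin cytoskeleton genes had medians of 0.55 and 0.13 over 23 genes (adjusted p = 2.32e-06, and adjusted p = 0.789 with an estimated correlation). In that list 0 passed over all genes and 4 were higher adjusted over the list alone: tropomyosin Tpm1 (0.88 and 1.52), filamin Flna (0.56 and 0.46), vinculin Vcl (1.07 and 0.59) and the nonmuscle myosin heavy chain gene Myh9 (0.55 and 0.44).

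Mesenchymal transcription factors and markers rose as a set as well, with medians of 0.77 and 0.23 over 14 genes (camera adjusted p = 9.46e-05, and adjusted p = 0.789 with an estimated correlation). Of them 0 passed over all genes and 4 were higher adjusted over the list alone, the transcription factor genes Snai2 (1.64 and 1.10), Zeb2 (0.94 and 1.19) and Twist2 (1.01 and 0.59) and the cadherin gene Cdh11 (0.63 and 1.16). The TGF-beta and BMP response list had medians of 0.70 and 0.28 over 23 genes (adjusted p = 9.46e-05, and adjusted p = 0.789 with an estimated correlation). There, 0 passed over all genes and 1 adjusted over the list alone, the BMP antagonist gene Grem1 (1.53 and 2.05), followed by Bambi (0.89 and 0.69), Ltbp1 (0.70 and 1.88) and Tgfbi (2.84 and 0.96).

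Insulin-like growth factor axis genes had medians of 0.42 in line 167 and 0.10 in line 365 over 18 genes (camera adjusted p = 0.00271, and adjusted p = 0.789 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 2 were higher, the receptor substrate gene Irs1 (1.01 and 1.29) and the binding protein gene Igfbp4 (1.33 and 0.99). The growth factor gene Igf2 went the other way, at -0.85 and -0.60. Inflammatory chemokine and cytokine genes had medians of 0.64 and 0.0048 over 21 genes (adjusted p = 0.00271, and adjusted p = 0.789 with an estimated correlation). Their 0 calls over all genes became 5 higher and 1 lower adjusted over the list alone, with the chemokine gene Cxcl12 at 1.99 and 2.81, the cyclooxygenase gene Ptgs2 at 1.62 and 1.78, the cytokine gene Lif at 0.89 and 0.76, and Cxcl2 lower at -0.91 and -1.86. The line 365 median of this list lay at the 54.4 percentile of random lists, and that of the insulin-like growth factor list at the 90.5 percentile.

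Of the mesenchymal lineage markers, 2 lists rose as sets. Adipogenic markers had medians of 0.49 and 0.12 over 9 genes (camera adjusted p = 0.00277, and adjusted p = 0.789 with an estimated correlation), with 0 past over all genes and 2 higher adjusted over the list alone. These were Pparg, the nuclear receptor that drives fat cell differentiation (2.42 and 2.70), and the fatty acid binding protein gene Fabp4 (1.02 and 0.65). Osteochondrogenic markers had medians of 0.40 and 0.06 over 7 genes (adjusted p = 0.0348, and adjusted p = 0.789 with an estimated correlation), with 0 past over all genes and 0 adjusted over the list alone, and the cartilage transcription factor gene Sox9 was at 0.73 and 0.85. The line 365 medians lay at the 89.3 percentile of random lists for the adipogenic list and at the 64.9 percentile for the osteochondrogenic list. The osteochondrogenic call ended after quantile normalization, after cyclic loess and without the cell line in the model (adjusted p up to 0.0788), and the adipogenic one with a filter at the 50th percentile (0.0750). Skeletal muscle markers (13 genes, adjusted p = 0.468) and epithelial markers (9 genes, adjusted p = 0.115) did not pass as sets, and 0 of their members passed over all genes. The keratin gene Krt19, at 1.85 and 2.68, was the 1 gene of both lists past when adjusted over the list alone.

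Replication genes fell as a set. The G1/S and DNA replication list had medians of -0.31 in line 167 and -0.21 in line 365 over 34 genes (camera adjusted p = 1.78e-05, and adjusted p = 0.789 with an estimated correlation). Of its members 22 were lower in both lines and 0 higher in both, and 0 passed either over all genes or adjusted over the list alone. The replication origin and helicase genes Cdc45 (-0.64 and -0.56), Cdt1 (-0.56 and -0.49), Orc1 (-0.77 and -0.50) and Mcm5 (-0.44 and -0.39) had the smallest p. The G2/M and mitosis list did not pass (33 genes, adjusted p = 0.110, and 0.0433 without the filter), with a median of -0.33 in line 167 and 0.13 in line 365. CDK inhibitors and pocket proteins did not pass either (9 genes, adjusted p = 0.279), and both lists had 0 members past over all genes or adjusted over the list alone.

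Interferon-stimulated genes fell as a set, with medians of -0.58 and -0.11 over 28 genes (camera adjusted p = 0.00271, and adjusted p = 0.789 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 2 were lower, Ifit3 (-1.48 and -1.31) and Ifit1 (-1.66 and -1.03), which encode antiviral RNA-binding proteins. Bst2, which tethers budding virus, was at -1.0 and -0.55, and the peptide transporter gene Tap1 at -1.22 and -0.52.

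The MYC and ribosome biogenesis list fell (camera adjusted p = 0.00717, and adjusted p = 0.810 with an estimated correlation), with a median of -0.0028 in line 167 and -0.43 in line 365 over 25 genes, at the 90.7 and 0 percentiles of random lists. Members past numbered 0 over all genes and 0 adjusted over the list alone, and Nop16 (-0.40 and -0.62) and Rrp9 (-0.35 and -0.50) had the smallest p. Cytosolic ribosomal protein genes passed the set test as lower, with medians of -0.14 and -0.07 over 19 genes (adjusted p = 0.0179, and adjusted p = 0.789 with an estimated correlation), but at the 11.0 and 13.2 percentiles of random lists, which is not extreme, with 15 of them lower in both lines and 0 past either way of adjusting, over all genes or adjusted over the list alone. The unfolded protein and amino acid stress list had medians of -0.10 and -0.18 over 20 genes (adjusted p = 0.0440, and adjusted p = 0.789 with an estimated correlation), at the 48.5 and 1.85 percentiles of random lists. Its members gave 0 calls over all genes and 0 adjusted over the list alone, with the stress-responsive gene Sesn2 at -1.21 and -0.72 and the asparagine synthetase gene Asns at -0.26 and -0.63. This call ended under 5 alternatives (adjusted p up to 0.149). Quantile normalization ended all 3 calls of these lists, the MYC and ribosome biogenesis call ended also without the cell line in the model (up to 0.0841), and the ribosomal protein call also without the intensity trend (up to 0.156).

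**Figure D3:**
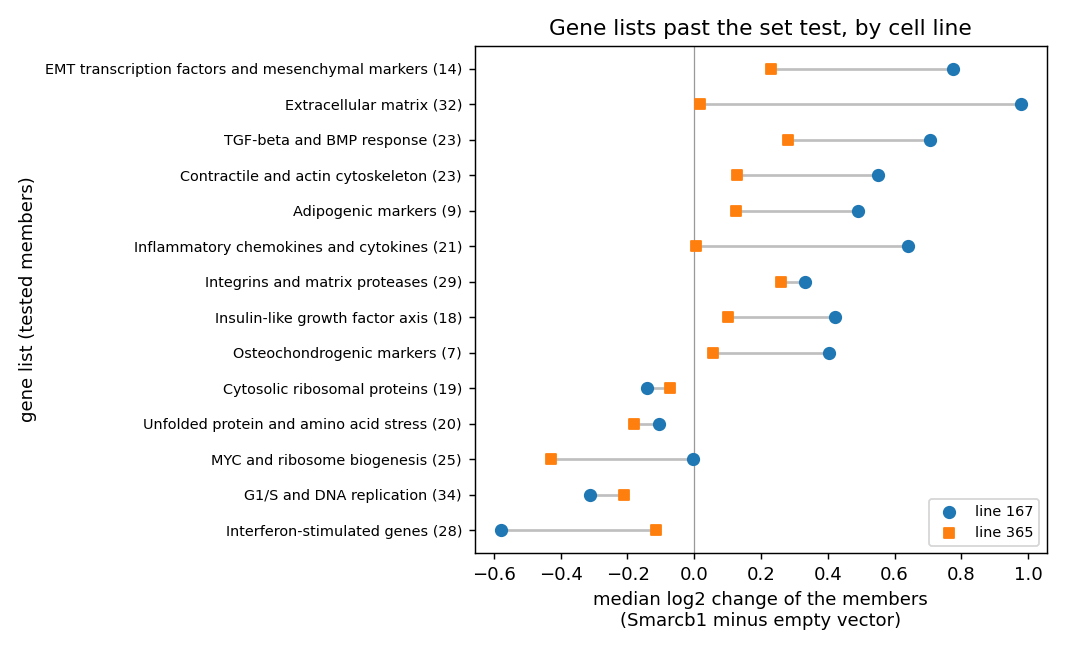
Median log2 change of the tested members (horizontal axis) of the 14 gene lists past the set test (vertical axis, number of tested members in brackets), with circles for line 167, squares for line 365 and a line joining the medians of a list. The widest gap is that of the extracellular matrix list, from 0.98 in line 167 to 0.02 in line 365.

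Among the remaining lists, given with their tested genes and camera adjusted p, SWI/SNF subunits did not pass (28 genes, 0.601), and Smarcb1 was the 1 member past over all genes and adjusted over the list alone. Polycomb subunits (25 genes, 0.279), p53 targets (20 genes, 0.179) and apoptosis regulators (17 genes, 0.995) had 0 members past either way, over all genes or adjusted over the list alone. Hedgehog genes (12 genes, 0.279) had 2 higher adjusted over the list alone, Hhip (2.52 and 1.39) and Gas1 (1.58 and 0.79), which encode proteins that bind Hedgehog ligands. WNT targets (16 genes, 0.438) had 2 higher and 1 lower adjusted over the list alone, the WNT inhibitor gene Apcdd1 (3.07 and 2.5), Wnt5a (0.82 and 1.18) and Dkk1 (-0.66 and -0.92). In the PI3K-AKT list (21 genes, 0.443) Deptor (1.03 and 1.63) and Pik3r1 (1.52 and 0.72) were higher and Inpp4b (-0.69 and -0.92) and Pik3r3 (-0.88 and -0.70) lower adjusted over the list alone. The EGFR-ERK list (24 genes, 0.108) had Phlda1 (1.49 and 2.22) and the hypoxia and glycolysis list (19 genes, 0.378) had Ndrg1 (3.22 and 2.09) and P4ha2 (1.18 and 0.81) past in this way. Neuronal markers split (21 genes, 0.807), with the tubulin gene Tubb3 (1.74 and 2.35) and Stmn2 (2.21 and 0.87) higher and Nefm and the synaptophysin gene Syp (-0.70 and -1.12) lower adjusted over the list alone. Imprinted growth genes (14 genes, 0.0570, and 0.0191 without the filter, with a call after cyclic loess too) had 1 lower, Nnat (-1.08 and -1.10). Notch (13 genes, 0.0665, and 0.0363 with camera on ranks), cholesterol synthesis (17 genes, 0.405) and HOX genes (29 genes, 0.807) had 0 past in this way. Of all members of these lists, Smarcb1 alone passed over all genes.

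Of the markers of other cell types, 9 of 13 endothelial and 5 of 16 macrophage and leukocyte markers were tested. Between the lines, 2 endothelial markers were higher in line 365 and 1 in line 167 (limma adjusted p below 0.05). Endothelial markers (9 genes, camera adjusted p = 0.556) and macrophage and leukocyte markers (5 genes, 0.970) did not pass and had 0 members past over all genes or adjusted over the list alone. The macrophage lysosomal gene Cd68 was at -0.64 in line 167 and -1.78 in line 365, and the leukocyte tetraspanin gene Cd53 at -0.33 and 2.21. The direction of the set test differed in sign from the median of the members for the neuronal, hypoxia and WNT lists and from their mean for the neuronal and macrophage lists.

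Some large changes were seen in 1 line with the other line within 0.25 of 0. There were 104 such genes higher and 77 lower in line 167, and 76 higher and 45 lower in line 365. In line 167 the largest increases of this kind were Gas6, a ligand of TAM receptors (3.91), the matrix glycoprotein gene Thbs2 (3.47), Pi15 (3.41), angiotensinogen (Agt, 3.29) and the WNT modulator gene Sfrp2 (3.28), and the largest decreases were Hacl1 (-2.61), Nptx1 (-2.41), the muscarinic receptor gene Chrm2 (-2.34), Car14 (-2.0) and the imprinted gene Mest (-1.84). In line 365 they were Havcr2, an immune checkpoint receptor gene (3.67), Clca3a2 (3.35), the urea transporter gene Slc14a1 (3.10), Tm6sf1 (3.09) and Rab7b (2.70) among increases, and the interferon-induced chemokine gene Cxcl10 (-2.54), Fam163a (-2.42), Optc (-2.36), Ccno (-2.35) and Paqr9 (-2.11) among decreases. The other line's control was below the filter level of 4.27 for Chrm2 (4.0) and Car14 (3.80) in line 365 and for Fam163a (3.42) and Paqr9 (4.10) in line 167, which left little room for a decrease there. Pi15 (3.39), Clca3a2 (4.18) and Rab7b (3.94) started from controls below it in their own line. Each rests on 1 array against 1, and the difference between the lines in response was not tested.

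Cell line separated far more genes than the vector did. Adjusted p was below 0.05 in limma for 1528 genes, 741 higher in line 365 and 787 higher in line 167, and 511 and 558 of these differed at least 2-fold. The split depended on scaling, with 942 higher in line 365 and 681 higher in line 167 after median centring. Line 365 had higher Ankrd1, a stress-responsive nuclear cofactor (log2 11.4 against 4.43, difference 6.96 ± 0.17 SE, adjusted p = 0.00223), the fibulin gene Efemp1 (6.63 ± 0.71, adjusted p = 0.0123), E-selectin (Sele, 6.32), Akr1b8 (5.35), the junctional adhesion gene F11r (5.23), Bcar3 (5.17), Asb4 and the activin antagonist follistatin (Fst, 5.06). Line 167 had higher Lox, the collagen cross-linking lysyl oxidase (11.4 against 3.83, adjusted p = 0.00223). The same held for the small leucine-rich proteoglycan genes Ogn and Aspn, the collagen receptor gene Ddr2 (-6.36, as line 365 minus line 167), the growth factor gene Ptn, Col12a1, Grb10 and Col5a2 (-5.90). Mean levels of Lox, Ogn and Aspn in line 365 and of Asb4 in line 167 lie below the filter level of 4.27, where signal above background was not shown, so the sizes of these 4 differences are uncertain. In line 167 the controls of Efemp1 (4.20) and F11r (4.07) and the Smarcb1 array of Bcar3 (4.26) lie below it too. Efemp1 changed by 2.73 in line 167 and -0.29 in line 365 with Smarcb1, so its line difference was not alike with both vectors. In the set test added after the data were seen, the MYC and ribosome biogenesis list was higher in line 365 (median 0.55, adjusted p = 5.07e-07, and adjusted p = 0.991 with an estimated correlation), as was the unfolded protein and amino acid stress list (median 0.68, adjusted p = 0.000233, and adjusted p = 0.991 with an estimated correlation). The arrays of a line are a control and a treated culture, not separate isolates, and the comparison concerns these 2 lines alone. With 1 array left out, in a fit without the vector, 236 genes passed without the line 167 control, 229 without the line 167 Smarcb1 array, 146 without the line 365 control and 267 without the line 365 Smarcb1 array.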

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

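Tests of array scaling, of Smarcb1 dose and of the share of infected cells, and the test on interferon genes, were chosen only after the result was seen.

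Opposite changes of at least 2-fold in the 2 lines drew attention to 6 genes, and the difference was not tested because 1 array stands for each line and vector. P3h2, a collagen prolyl hydroxylase gene, changed by 2.08 in line 167 and -2.30 in line 365, Esm1 by 1.34 and -2.21, and the growth factor gene Tgfb2 by 1.12 and -1.35. Kcnh5 changed by -1.61 and 1.23, Ap1s3 by -1.15 and 1.46, and the transcription factor gene Lhx9 by -1.13 and 1.12. The G2/M and mitosis list had a median of -0.33 in line 167 and 0.13 in line 365, at the 0 and 99.5 percentiles of random lists, and this difference was not tested either. Outside the named genes, 20 of 5923 probe sets that the annotation does not list were at least 2-fold higher in both lines, with 4 lower and 10 opposite, as were 5 of 1010 probe sets with several gene symbols, with 0 lower and 0 opposite.

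Large changes shared by the lines ran upward, with 186 genes at least 2-fold higher and 26 lower, or 87.7% higher. Under median centring, quantile normalization and cyclic loess the share was at least 81.9%. The deposited values were already quantile-normalized, and these settings shifted them little. The median change of all tested genes was -0.105 with median centring, -0.032 with quantile normalization and -0.0024 with cyclic loess, against -0.032. Such shifts could alter counts at a 2-fold limit only a little. The test therefore cannot decide whether array scaling gave the skew, and array scaling stays open. Dim probe sets with no room to fall could give such a skew. Among genes above the median of mean signal, 69 were higher and 12 lower, a share of 85.2%. The exact 95% interval was 75.6 to 92.1%, which treats genes as independent. That mean covers control and Smarcb1 arrays alike, so a gene with a dim control and a strong rise can enter the group. The test therefore cannot decide whether dim controls gave the skew, and this explanation stays open. The 2-fold changes of 1 line alone ran upward too (180 higher and 122 lower), while the skew was weaker at 1.5-fold in both lines (390 and 189) and was not seen at 1.5-fold in 1 line alone (566 and 722) or among the 1613 genes at an unadjusted p below 0.05 (793 lower). Its cause was not tested.

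Changes were larger in line 167, with an SD across genes of 0.54 against 0.46 in line 365. Less Smarcb1 transcript in line 365 was not seen, as its change there was larger by 0.38. That difference rests on 1 array for each line and vector and was not tested, and transcript is not protein. The Smarcb1 signal was also higher in the line 365 control, at log2 6.01 against 4.61 in the line 167 control. Whether this bears on the size of the changes was not tested. A smaller share of infected cells could contribute and stays open, since 42.5% of the genes at least 2-fold higher by mean change (156 of 367, exact 95% interval 37.4 to 47.7%, genes taken as independent) changed more in line 365, a test that with its bounds replaced an earlier one (47.0%, 87 of 185) whose genes had to be 2-fold higher in line 365. As a group the 104 genes higher in line 167 alone were not already high in the line 365 control. Their median control level was 5.36 in both lines, against 7.07 with Smarcb1 in line 167. Of them, 40 (38.5%) had a line 365 control level no more than 1 log2 unit below the line 167 Smarcb1 level, as did 92.5% of all tested genes. A gene that rose little more than 2-fold can meet this limit without a high control. Whether a high control explains a part therefore stays open. A difference between the tumours stays open, as it was not tested.

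Interferon-stimulated genes were lower with Smarcb1, and a high interferon response in the line 167 empty-vector array alone is a candidate explanation. The list median in line 365 lay at the 5.95 percentile of random lists, which is not extreme, but 3 of 28 members were at least 2-fold lower in line 365, where 0.327 would be expected from all genes. The explanations cannot be told apart with 1 array for each line and vector.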

How the results depend on the processing

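None of these alternatives was chosen after the data were seen. The count of 9 genes raised by Smarcb1 became 68 (64 higher, 4 lower) without the filter, 101 (91 and 10) with a filter at the 50th percentile, 71 (67 and 4) after quantile normalization, 28 after cyclic loess and 103 at an adjusted p below 0.10. All 9 were among them except under the 50th percentile filter, which kept 7 and removes Akr1c18 and Serpinb1a by their signal. Prior degrees of freedom went from 3.75 to 4.65, 4.52, 4.22 and 3.82 in the first 4, and the cause was not tested further. Without the replicate block (the pairing by cell line) 0 genes passed limma's test and 450 had an unadjusted p below 0.05, and with each array left out of that fit 0 to 0 passed, with 325 to 514 unadjusted. Serpinb1a was also lost without the intensity trend. Line differences numbered 2915 at an adjusted p below 0.10 and 146 to 267 with an array left out. Genes changed 1.5-fold the same way in both lines numbered 579 (390 higher, 189 lower, 69 opposite), and line-specific changes 187 with the 50th percentile filter and 1288 at 1.5-fold. With an estimated inter-gene correlation 0 lists passed, while the other settings gave 10 to 16, 11 of them without the block. The correlation of the lines' changes ranged from 0.368 to 0.495. In the fits that held both lines, the direction of the mean change was checked for the 85 genes named in the Smarcb1 comparison. Genes named only for line differences or for opposite or line-specific changes were not checked in this way. Among the 85 genes, the mean change turned direction only for values near 0 that passed nowhere. These were Ccnd1 with median centring (-0.064), Cdkn2a with quantile normalization (0.0022) and cyclic loess (0.0225), and Ezh2 with cyclic loess (0.00983). With a line left out, signs were compared only for genes past the main test. Other named genes had opposite signs in the lines, such as Ptch1 (0.67 in line 167 and -0.36 in line 365). Set tests that turned, by adjusted p, were those of neuronal markers (0.877 without the filter, 0.886 quantile, 0.837 loess), macrophage markers (0.865 quantile, 0.827 loess, 0.943 without the block), apoptosis regulators (0.886 quantile, 0.827 loess, 0.980 on ranks, 0.943 without the block) and HOX genes (0.943 without the block), and the cause was not tested. Median centring put the median change of all tested genes at -0.105, against -0.032. Leaving out a line leaves no residual, so only the other line's values remain, and single genes were not refitted with 1 array left out. Signal over background limits what can be said of genes near the filter.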

Other observations

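The test on control levels was written before its result was seen, and the genes named in the next paragraph were chosen after their values were seen.

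Some matrix and smooth muscle genes with large line 167 changes had little counterpart in line 365, while others, such as Fn1 (3.90 and 2.48) and Tnc (2.93, from a dim control at 3.99, and 2.48), were higher in both lines. The smooth muscle actin gene Acta2 changed by 4.70 in line 167 and -0.68 in line 365, Tagln by 3.43 and 0.40, and the collagen gene Col1a1 by 2.65 and 0.03. None of these 5 genes passed the test over all genes in limma, and the difference between the lines was not tested.

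Genes raised by Smarcb1 may be ones that are poorly expressed in Smarcb1-deficient cells of another tumour too. Genes at least 2-fold higher in line 167 had a median control level in line 365 at the 29.7 percentile of tested genes, and those higher in line 365 had a median at the 33.7 percentile in the line 167 control. Genes at least 2-fold lower lay at the 41.9 and 43.0 percentiles. The controls of the lines resemble each other and a gene with a low control has more room to rise, so the test does not separate repression in the absence of Smarcb1 from that.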
